A study of Mus musculus with 6 samples.

How the data were processed

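RNA from mouse hearts was sequenced from 3 young and 3 old animals, all labelled wild type and untreated. Per the labels' protocols, RNA was extracted with a mirVana kit and libraries were made with a TruSeq Stranded mRNA kit, which selects polyadenylated transcripts. The ages in months, the strain and the sex are not given in the labels. The titles number the mice 1 to 3 in each group, and these numbers were taken as names of separate animals.

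The deposited gene counts are whole numbers per gene and library, and the deposited FPKM values (counts scaled by gene length and library total) were made by the authors from the same counts. Per the submitters' processing notes, Trimmomatic, HISAT2, Bowtie2, HTSeq, Cufflinks, StringTie and DESeq were used with the GRCm39 build; versions, the role of each tool and the strand setting of the counting are not given in the sources used here. All 12 per-sample files equalled their column in the tables of all samples. Dividing the counts by FPKM and by the library total gave a single whole-number length for each of the 16964 genes with counts, within a relative deviation of 1e-06. The tables list 18005 gene symbols, of which 1041 had no count in any library. Of these symbols, 17887 matched the RefSeq gene table of the GRCm38.p6 assembly, 17730 as protein-coding. No mitochondrially encoded gene and no Xist is among the listed symbols, so neither was analysed here. The reference used here is an older build than the one in the notes, so no coordinates are given.

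Library totals ranged from 11295280 to 12514005 counts, so that 1 count is worth about 0.084 CPM (counts scaled to a fixed library total). Replicates of a group differed by more than sampling noise, with a chi-square per degree of freedom between 7.9 and 16.7 for genes with at least 20 counts over the pair.

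Genes were tested with edgeR 4.0.16 in R 4.3.3 with the quasi-likelihood F test on the deposited counts, after filterByExpr and TMM normalization, over all 6 libraries with no covariate. Adjusted p-values are Benjamini-Hochberg values over the 12893 genes tested, and a gene was called at an adjusted p under 0.05. Fold changes are log2 of old over young, so a positive value is higher in old hearts. Standard errors were derived from the fold change and the F statistic. CPM values are TMM scaled and given as mean ± SD with n = 3 mice per group. Where HTSeq or another counter had to place reads shared by near-identical copies, the split between the copies is uncertain. This holds for Hspa1a and Hspa1b, the globin genes, Myh6 and Myh7, Amy1, the Klk1b, Gbp and Ifit families, and Entpd4 with Entpd4b. Antisense or overlapping genes cannot be separated without the strand setting.

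Before the data were examined, 49 gene lists were written from textbook knowledge of heart tissue, and 42 of them had at least 5 tested members. These were tested with camera at a preset correlation of 0.01, 2-sided, with Benjamini-Hochberg adjustment over the 42 lists. Beside it stand the members called over all genes, the members called when adjusted over the list alone, camera with a correlation estimated per list, and fry. Library measures were compared with an exact 2-sided permutation test of the difference in means, which cannot give a p below 0.1 with 3 against 3.

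The genes named were fixed by rule. They are the 10 largest rises and the 10 largest falls among called genes with a mean log2 CPM of at least 1 and no overlap between groups, without predicted genes, unnamed Riken clones, pseudogenes and variable segments of immune receptors. Added to them are the 5 genes of smallest p, up to 4 called members per list by smallest p (or the 2 most expressed where none was called, values only), and a fixed set of heart, collagen, cell cycle inhibitor and sex-linked genes reported whatever their result. Genes outside this rule are named as chosen after their values were seen. Some genes that the rule takes are not reported here.

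Alternatives fixed before the data were examined were RLE, upper-quartile and library-size scaling, no filter, a filter of 1 CPM in 3 libraries, a block for the replicate number, each library left out, the 10 most abundant genes left out, limma-voom (limma 3.58.1) with and without quality weights, limma on log2 of the deposited FPKM with pseudocounts of 1 and 0.1 for genes with a mean FPKM of at least 1 and with no filter, DESeq2 1.42.0, and other thresholds. Removal of gene length trends, removal of GC content trends (loess, span 0.5) and omission of the 4 globin genes were added after seeing the data.

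The gene test was checked on simulated counts for the old against young comparison over 12787 genes. It recovered 68.8% of genes changed 1.5-fold, 83.7% of those changed 2-fold, 98% of those changed 3-fold and 100% of those changed 5-fold, and 7.1% of its calls were unchanged genes. In a second simulation over the 42 lists, with a 1.5-fold shift of the oxidative phosphorylation list, that list was called and 0 others were. Genes were drawn independently there: the estimated correlation of that list was -0.011, against 0.45 in the data. The simulation therefore cannot show how often lists of correlated genes are called without a shift. In another simulation, over 12772 genes with a length trend and no other change, the correction lowered the calls from 615 to 2.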

Results

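Transcript levels were measured by RNA sequencing in hearts of 3 young and 3 old wild-type mice. The series title places the comparison in age-related cardiac hypertrophy. Totals per library lay between 11295280 and 12514005 counts. Total counts, genes detected, the ribosomal protein share and the globin share overlapped between the groups. The 10 most abundant genes took 10.17% ± 0.0418 of the counts in young and 11.23% ± 0.109 in old libraries (SD, n = 3), without overlap (exact 2-sided permutation p = 0.1, the smallest possible).

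Old hearts had far higher levels of the chaperone genes Hspa1a and Hspa1b and of several immediate early genes, and far lower levels of Myh7 and Nppa. Hspa1b, an inducible Hsp70 chaperone, rose from 5.1 ± 1.56 to 563 ± 47.2 CPM (SD, n = 3), a log2 fold change of 6.77 ± 0.17 (SE, edgeR adjusted p = 9.9e-10). Myh7, the slow beta myosin heavy chain, fell from 4160 ± 484 to 147 ± 100 CPM, a log2 fold change of -4.83 ± 0.42 (edgeR adjusted p = 1.8e-05). Nppa, which encodes atrial natriuretic peptide, fell from 384 ± 42.7 to 77 ± 32.4 CPM (log2 fold change -2.32 ± 0.23). In total 2835 of 12893 genes were called by edgeR, 1467 higher and 1368 lower in old hearts, and 291 and 157 of these changed at least 2-fold. The groups did not overlap for 39.9% of the tested genes, against 10% given by chance.

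The other largest rises were those of Hspa1a (log2 fold change 6.57 ± 0.21), the nuclear receptor gene Nr4a3 (4.8 ± 0.27), Arc (4.5 ± 0.53), Lypd8l (4.2 ± 0.36), Fosb (4.09 ± 0.25), the stress-responsive factor Atf3 (4.02 ± 0.33), the potassium channel gene Kcnk1 (4.02 ± 0.36), Klk1b26 (3.87 ± 0.52) and Fos (3.81 ± 0.78). Other large falls were those of Cyp26b1, a retinoic acid hydroxylase (-3.57 ± 0.28), Scgb1c1 (-2.74 ± 0.2), Fam124b (-2.67 ± 0.33), the apelin receptor gene Aplnr (-2.65 ± 0.27), the aromatic amino acid decarboxylase gene Ddc (-2.57 ± 0.34), the growth factor gene Nrg1 (-2.39 ± 0.23) and Tmem171 (-2.26 ± 0.22). Hspa1a and Hspa1b are near-identical, and their sum was 10.15 ± 2.76 CPM in young and 1042 ± 122 in old hearts. Besides these and Dnajb1, the genes of smallest p included Bdh1, an enzyme of ketone body use (2.12 ± 0.08), and Amy1 (2.05 ± 0.11). Each of these genes was called by edgeR whichever library was left out. Fos had 31.87, 47.79 and 332.35 CPM in the old libraries, and without old 3 its log2 fold change was 2.04 and that of Arc 3.68. Other values that moved by over 1.5 times grew: Lypd8l to 4.79 without young 1, Myh7 to -5.49 without old 1 and Cyp26b1 to -4.31 without old 2.

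**Figure D1:**
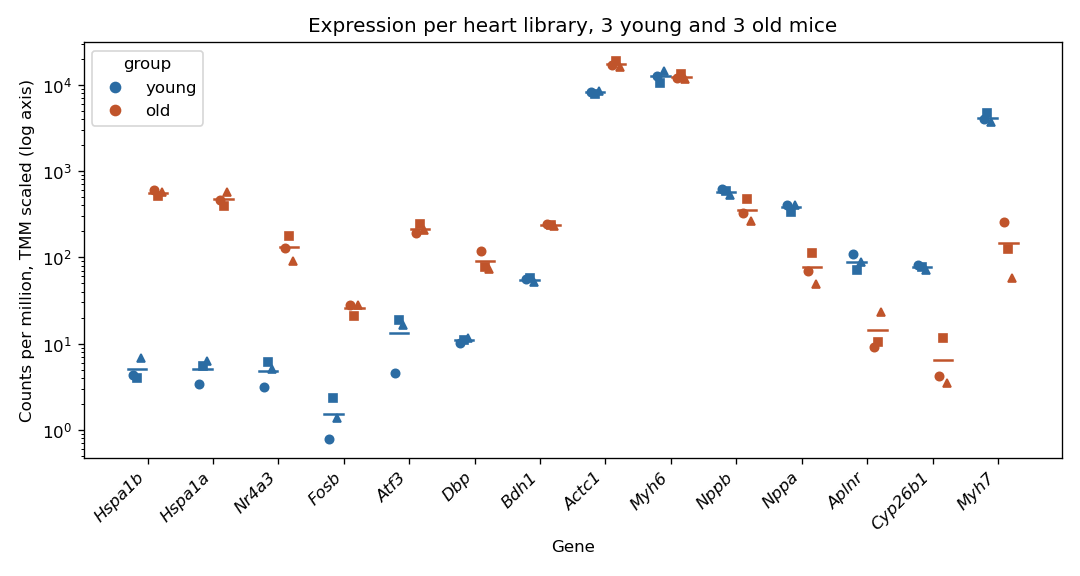
TMM-scaled CPM (log axis) of selected genes in each of the 3 young and 3 old libraries, with a bar at each group mean and marker shapes for the replicate number. Hspa1b averages 5.1 CPM in young and 563 in old hearts, Myh7 4160 and 147, while the groups overlap for Myh6.

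Without library young 1 the number of called genes was 1557, and without young 3 it was 1552. The direction split depended on the scaling: 51.7% of calls were higher in old hearts under TMM, 40.2% with upper-quartile factors, 32.7% with library size alone and 35.1% on the deposited FPKM values.

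Most immediate early genes and 17 of 32 heat shock genes rose. Of 26 immediate early genes, 24 rose and 0 fell, with a median log2 fold change of 1.99 (26 higher when adjusted over the list alone). Fosl2 rose by 1.87 ± 0.11 and Ier5 by 1.56 ± 0.09. Of 32 heat shock and unfolded protein response genes, 17 rose and 0 fell, including the cochaperone gene Dnajb1 (2.97 ± 0.13) and Hspb1 (1.8 ± 0.1), with 19 higher when adjusted over the list alone. Of 18 glucocorticoid and fasting responsive genes, 13 rose and 0 fell, among them Cebpb (1.76 ± 0.13) and Fkbp5 (1.46 ± 0.16); 13 were higher and 2 lower when adjusted over the list alone, and 2 fell without old 3. Of its members, 11 are in no other list, and 8 of those rose. Camera at the preset correlation of 0.01 called these lists with adjusted p = 2.3e-39, 5e-24 and 1.6e-12. The correlations estimated from the data were 0.48, 0.28 and 0.14, and with them camera gave adjusted p = 0.26 for each list. The small p-values therefore do not allow for how far the members of a list varied together. Library old 3 stood apart in the list medians, taken relative to the young mean on the log2 scale. Its median over immediate early genes was 2.84, against 1.45 in old 1 and 1.38 in old 2. That over heat shock genes was 0.22 against 0.59 and 0.44. Single members did not all follow these medians. Among the old libraries Hspa1a (576.31 CPM) and Dnajb1 (264.15 CPM) were highest in old 3, and Hspb1 (613.75 CPM) was lowest there. Fosb was highest in old 3 (28.17 CPM against 27.8 and 20.74), but Nr4a3 was lowest (90.04 CPM against 128.82 and 178.79).

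Clock genes changed in both directions. Of 20 tested, 10 rose and 4 fell (12 and 4 when adjusted over the list alone; camera adjusted p = 6.1e-07, and adjusted p = 0.39 with an estimated correlation). Dbp, a clock output factor, rose by 3.04 ± 0.18, Bhlhe40 by 1.89 ± 0.12, Per1 by 1.97 ± 0.18 and Nr1d1 by 1.17 ± 0.1. The lower genes included Arntl (-1.65 ± 0.21), Npas2 (-1.6 ± 0.27) and Clock (-0.28 ± 0.08), which were named after their values were seen. The median over clock genes, relative to the young mean on the log2 scale, was 0.12 in old 3. It was 0.77 in old 1, 0.56 in old 2 and 0.05 in young 3. This median pools genes of both directions. The rising genes named above lay above every young library in old 3 too, as with Dbp at 74.18 CPM against at most 11.69.

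Part of the genes of mitochondrial energy metabolism rose, most of them by small amounts, and the majority of each list was not called. Of 52 nuclear genes of oxidative phosphorylation, 17 rose and 0 fell (31 higher when adjusted over the list alone), with a median log2 fold change of 0.23. Atp5d rose by 0.4 ± 0.08, Cyc1 by 0.37 ± 0.08, Cycs by 0.52 ± 0.11 and Uqcrfs1 by 0.37 ± 0.08. Camera gave adjusted p = 1e-05, and adjusted p = 0.96 with an estimated correlation, and fry's directional adjusted p was 0.056. The count was 3 without young 1, 4 without young 3, 11 without old 1 and 30 without young 2. After removal of the gene length trend the count was 9 and camera's adjusted p = 0.086 (over the alternatives 1.6e-10 to 0.96). Of 43 genes of fatty acid uptake and oxidation, 11 rose and 1 fell (16 and 3 adjusted over the list alone; adjusted p = 0.018, and adjusted p = 0.73 with an estimated correlation). Fabp3, a fatty acid binding protein gene, rose by 0.55 ± 0.09, Cpt2 by 0.54 ± 0.08 and Acaa2 by 0.44 ± 0.08. The fatty acid list had 4 higher genes without young 1 and 7 without old 1, and was not called without old 2 (adjusted p = 0.054) or old 3 (adjusted p = 0.092; over the alternatives 0.004 to 0.73), where 3 and 4 genes fell. Of 19 tricarboxylic acid cycle genes, 5 rose and 1 fell (8 and 1 adjusted over the list alone), with Idh3a at 0.47 ± 0.09 and Suclg1 at 0.38 ± 0.08. This list passed narrowly (adjusted p = 0.047, and adjusted p = 0.9 with an estimated correlation) and was no longer called without any 1 of the libraries except old 3; 2 genes rose without young 1, and 3 without young 3 or old 1. Of 30 glucose uptake and glycolysis genes, 9 rose and 2 fell, with Pfkfb1 at 1.86 ± 0.16, and the list missed the threshold (adjusted p = 0.06). It passed without young 3 (0.029), old 1 (0.033) and old 3 (0.021), narrowly without young 1, with no filter and with limma-voom (0.038), and over all alternatives its adjusted p ranged from 0.021 to 0.99. The 9 higher genes were 3 without young 1, young 3 or old 2, 5 without young 2 and 4 without old 1. The 2 falls were 0 without young 1, young 3 or old 1, and 1 without young 2 or old 3.

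In the chemokine, complement and antioxidant lists more genes rose than fell, and in the interferon list the called genes fell. Of 22 chemokine and cytokine genes, 13 rose and 1 fell (13 and 1 adjusted over the list alone; adjusted p = 1.6e-05, and adjusted p = 0.39 with an estimated correlation), with Ccl11 at 2.26 ± 0.19, Ccl8 at 1.74 ± 0.19 and Cxcl14 at 1.29 ± 0.16, and Tnfsf10 lower at -1.37 ± 0.2. Of 17 complement genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone; adjusted p = 0.0019, and adjusted p = 0.39 with an estimated correlation), with C4b at 1.25 ± 0.1. Of 30 antioxidant and metallothionein genes, 15 rose and 1 fell (20 and 1 adjusted over the list alone; adjusted p = 3.1e-05, and adjusted p = 0.39 with an estimated correlation), the fall being lost whichever library was left out, with Mt2 at 1.27 ± 0.18, Hmox1 at 0.99 ± 0.14 and Mt1 at 0.91 ± 0.1. Of 32 interferon response genes, 0 rose and 11 fell (1 and 11 adjusted over the list alone), among them Rsad2 at -1.4 ± 0.1 and Ifit2 at -0.63 ± 0.13. Camera gave adjusted p = 0.00065, and adjusted p = 0.96 with an estimated correlation, and fry's directional adjusted p was 0.21. Without young 2, 6 interferon response genes fell, and without young 3, 7 fell; without old 3, 3 rose. Without young 3 the higher genes numbered 8 in the chemokine list, 5 in the complement list and 8 in the antioxidant list. In the chemokine list 2 genes fell without old 1.

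More genes of senescence and of matrix turnover rose than fell. Of 20 genes of senescence and its secretory phenotype, 7 rose and 2 fell (8 and 2 adjusted over the list alone; adjusted p = 0.0016, and adjusted p = 0.4 with an estimated correlation). Plaur rose by 1.89 ± 0.2 and the cell cycle inhibitor gene Cdkn1a by 1.59 ± 0.18, and Igfbp3 was lower at -0.76 ± 0.13. Cdkn2a was higher at 1.55 ± 0.39, at 0.622 ± 0.278 CPM in young and 1.83 ± 0.436 in old hearts, a call lost without young 1 (edgeR adjusted p = 0.066). Of 25 genes of matrix turnover and TGF-beta signalling, 8 rose and 2 fell (10 and 2 adjusted over the list alone; adjusted p = 0.0038, and adjusted p = 0.39 with an estimated correlation), with Adamts1 at 1.81 ± 0.21, Timp3 at 0.96 ± 0.13 and Serpinh1 at 0.91 ± 0.1. The matrix turnover list was not called with limma-voom (adjusted p = 0.052; over the alternatives 0.00052 to 0.39) or on FPKM values, and its 2 falls were 0 without young 1 or old 1 and 1 without young 2, young 3 or old 2. Of 34 extracellular matrix genes, 5 rose and 4 fell: Thbs1 was higher at 2.76 ± 0.19 and Postn at 0.59 ± 0.1, and elastin (Eln) lower at -1.22 ± 0.12. Col3a1 fell (-0.66 ± 0.12), and Col1a1 did not pass the test (-0.16 ± 0.11, edgeR adjusted p = 0.35).

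**Figure D2:**
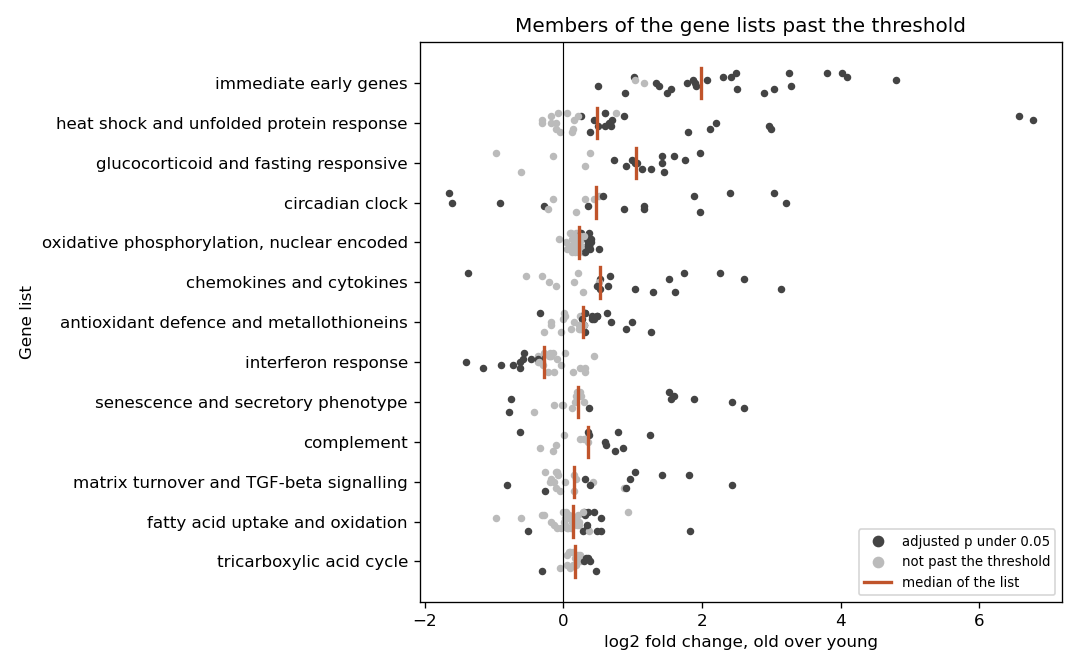
Log2 fold change, old over young, of each tested member of the 13 gene lists past the threshold, with called members dark and the list median as a bar. The median is 1.99 for immediate early genes, 0.23 for oxidative phosphorylation and -0.28 for interferon response genes.

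Markers of hypertrophy and sarcomere genes went both ways. Of 15 natriuretic peptide and hypertrophy genes, 5 rose and 6 fell, and 3 rose without young 1. Xirp1 rose by 1.49 ± 0.12 and Fhl2 by 1.04 ± 0.1, and Nppb fell (-0.7 ± 0.17), a call lost without young 1 and without old 1, and with DESeq2. Acta1 had 0.39 ± 0.17 and did not pass (edgeR adjusted p = 0.12). Of 22 sarcomere genes, 6 rose and 6 fell, with Tcap at 1.46 ± 0.13, Actc1 at 1.08 ± 0.08 and Tpm1 at 0.43 ± 0.08, and Myom2 lower at -1.81 ± 0.14. Myh6, the fast alpha myosin heavy chain, was at 12500 ± 2070 CPM in young and 12400 ± 859 in old hearts (-0.02 ± 0.11, edgeR adjusted p = 0.94). Myh7 made up 25.2% ± 5.32 of Myh6 and Myh7 together in young and 1.17% ± 0.816 in old hearts (SD, n = 3, exact permutation p = 0.1). Of 30 calcium handling and ion channel genes, 8 rose and 6 fell (5 to 8 and 3 to 5 with a library left out, lowest for the falls without young 1, young 3 and old 1), with Kcna5 higher at 0.86 ± 0.1 and Kcnj2 lower at -1.48 ± 0.15. Atp2a2, the calcium pump of the sarcoplasmic reticulum, was higher at 0.32 ± 0.09, a call held in 2 of the 6 fits with a library left out and lost with library size alone and on FPKM values.

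No marker list of another cell type that was tested passed camera's test in the unpaired edgeR fit of all 6 libraries. The neutrophil, adipocyte, skeletal muscle, lung and thymus lists had fewer than 5 tested members and were not put to this test. Of 21 macrophage markers, 5 rose and 1 fell (8 rose without old 3, and 2 fell without old 1). Lyve1 was higher at 0.88 ± 0.11 and Mertk at 0.83 ± 0.15, and Cx3cr1 lower at -2.15 ± 0.18. Of 9 epicardial and mesothelial markers, 1 rose, Wt1 at 1.67 ± 0.13, and 2 fell without young 2. The median of this list varied within the young group. Relative to the young mean on the log2 scale it was 1.22 in young 1 and -1.55 in young 2. Among endothelial markers Rgcc rose (1.02 ± 0.11) and Tek fell (-0.5 ± 0.1). Of 9 red blood cell markers 0 rose and 1 fell, Hba-a2 at -1.51 ± 0.5. This call was lost without young 2, young 3, old 1 or old 2 and with limma-voom, DESeq2 and FPKM values. The log2 fold change of Hba-a2 was -0.74 without young 2. Without young 1 all 9 fell and the list passed (adjusted p = 3.4e-10), without old 2 it passed with 0 genes called (0.049), and over all alternatives its adjusted p ranged from 3.4e-10 to 0.99. The globin share was 0.217% in young 1 and 1.56% in young 2. Of the 85 ribosomal protein genes 0 were called by edgeR, by DESeq2 or by limma-voom, with 1 at an unadjusted edgeR p under 0.05, and Rplp0 stood at -0.06 ± 0.11. The Y-linked gene Ddx3y was detected in every library (49.74 to 67.92 CPM), at 56.3 ± 2.39 CPM in young and 58.5 ± 9.11 in old hearts. Eif2s3y, also Y-linked, ranged from 31.19 to 41.29 CPM. Y-linked transcripts were thus present in each of the 6 hearts.

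Other lists held called genes of different direction. Adra1b was higher at 0.66 ± 0.12, and Adcy6 and Adrb1, the main cardiac beta receptor gene, were lower at -0.68 ± 0.1 and -0.75 ± 0.15. Among growth signalling and cardiac transcription factor genes Irs2 was at 2.07 ± 0.3, Hand2 at 1.32 ± 0.14 and Insr at -0.5 ± 0.1. Map1lc3a of autophagy was at 0.55 ± 0.08 and Atg14 at -0.65 ± 0.12, Pcna of the cell cycle at 0.43 ± 0.09 and Mcm7 at -0.54 ± 0.12. Tfrc, the transferrin receptor gene, was at 1.57 ± 0.24 and Bcl2l1 at 1.09 ± 0.1. Of the vessel wall markers Pdgfrb was at -0.69 ± 0.11 and Smtn at 0.52 ± 0.08. Of 7 lymphatic markers 1 rose and 1 fell: Lyve1, also in the macrophage list, at 0.88 ± 0.11 and Prox1 at -0.95 ± 0.1. Tbx3 of the conduction system was at 1.22 ± 0.11 and Gja5 at -0.99 ± 0.14. Each gene named in this paragraph was called by edgeR whichever library was left out. Counts per list were less stable: 6 of 15 smooth muscle and pericyte markers rose, but 1 without young 3 and 3 without young 1, young 2, old 2 or old 3. Of 26 autophagy genes 6 rose, but 2 without young 1 and 3 without young 3 or old 1. Of 22 adrenergic, angiotensin and endothelin genes 6 rose, but 2 without young 1 and 3 without young 2 or young 3.

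Camera called 13 of the 42 lists, 12 higher and 1 lower, and missed the threshold for the other 29. With an estimated correlation 0 lists were called, with 4 at an unadjusted p under 0.05, and fry called 11 directionally.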

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

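No named gene that was called in the reported or an alternative fit changed direction between them, and 126 of the 156 named genes that were called stayed called by edgeR whichever library was left out. Leaving out 1 library gave 1552 to 3041 called genes, 850 to 1597 of them higher and 682 to 1444 lower in old hearts, and 12 to 14 called lists; the fits have fewer samples. Thresholds alone gave 1255 genes (724 higher, 531 lower) at an adjusted p under 0.01, 448 (291 and 157) with a 2-fold change added, 489 (310 and 179) at an unadjusted p under 0.05 with 2-fold, and 4642 (2308 and 2334) at an unadjusted p under 0.05. Library size alone gave 2122 lower genes, and limma on FPKM gave 907, 897 (pseudocount 0.1) and 810 (no filter) higher genes. These fits carry no TMM scaling, whose factors were 1.01 to 1.04 in young and 0.955 to 0.988 in old libraries. The median log2 fold change over all genes was -0.087 with library size alone. It was -0.08 to -0.025 on FPKM, against -0.006 under TMM. Other differences of the FPKM fits were not tested. With the correlation estimated per list, 0 lists were called. With the gene length trend removed, chosen after seeing the data, the ribosomal protein list turned to lower in old hearts (adjusted p = 0.0027), while without young 2 it was called higher (0.0076), and over its alternatives its adjusted p ranged from 0.0027 to 0.99; the cause was not tested. No clear pairing by replicate number was seen, though it is not excluded. Deviations of same-numbered libraries correlated at 0.078, 0.078 and 0.0067, and 4 of 6 libraries correlated best with their own number. The replicate block gave 2734 genes (1417 higher, 1317 lower) and 13 lists, without the tricarboxylic acid cycle list (adjusted p = 0.078, over its alternatives 0.003 to 0.9) and with the red blood cell list (0.025, over its alternatives 3.4e-10 to 0.99); of the named genes Atp2a2, Hba-a2 and Dnm1l were not called under the block and Atp2a1 was. Leaving out mitochondrially encoded genes was not run, as none is listed. In counts simulated with the mice, spread and depth of this design, 68.8% of 1.5-fold changes were recovered, so small changes can be missed. The simulation left 12593 of its 12787 genes unchanged. Recovery in the data, where 2835 genes were called, may differ.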

Other observations

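Several genes were found in a single library, by a rule chosen after seeing the data (at least 30 counts in 1 library and at most 2 in each other). The fast skeletal myosin genes Myh4 and Myh1 had 109 and 56 counts in young 3, Entpd4 had 89 counts in young 3, Serpinb2 had 40 in old 1, C1rb had 34 in old 3 and Gc had 31 in young 1. The old libraries also differed among themselves in genes picked after their values were seen. Old 3 had 814.02 CPM of Egr1 against 84.11 in old 1 and 101.71 in old 2, and 101.22 CPM of Hsph1 against 372.82 and 306.68.

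The tests below on time of day, handling, Myh6 and Myh7 reads, atrial tissue, exchanged labels and the gene length and GC trends were chosen after the result was seen, as were the single-library rule and the use of left-out libraries in the trend tests; the tests on a single old library and on splits were set before they were run. Immediate early and heat shock genes were called only higher in old hearts, and clock genes in both directions. A single old library as the source is argued against, since 23 of the 24 called immediate early genes stayed called whichever old library was left out. Collection at another time of day is a candidate explanation for the clock part: the 13 called genes assigned to an arm followed the opposition of the arms, with 3 activator genes lower and 10 genes of the other arm higher. Of the 14 called clock genes 1 was assigned to neither arm and not used in this test. Handling of the hearts before freezing also stays open, as 3 of 3 old libraries lay above every young one in the median of immediate early genes, which any difference shared by the old samples would give. Age itself stays open and was not separated from either, as the labels give no collection times.

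Myh7 and Nppa were lower in old hearts. Less atrial tissue in the old samples is argued against for Nppa, because Myl7, Myl4 and Sln together reached at most 1.42% of the Nppa level in a young library. Of 10 atrial markers 3 rose and 3 fell. Mybphl fell with Nppa (log2 fold change -2.88 ± 0.53, from 1.36 to 0.174 CPM, and -3.79 without old 2). Reads of Myh7 counted at Myh6 are argued against as the whole cause, since the sum of both genes differed by -4150 CPM (SE 1050), about the 4010 that Myh7 lost, and Myh6 by -138 (SE 1290). A partial shift cannot be told apart, because the bound set for it, a Myh6 gain of 2010 CPM, lies within 2 standard errors. An exchange of the group labels stays open. Cdkn2a was higher in 3 of 3 libraries labelled old, with counts of 21, 16 and 26 against 4, 8 and 11 in young. The minimum count set for the test was missed only in young 1 and young 2. Correct labels would also give low counts there, so the test cannot decide. Age stays open as an untested explanation.

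Of 52 oxidative phosphorylation genes 17 were called higher in old hearts, and shorter genes tended to be higher (Spearman rho of fold change and length -0.25 across genes, which are not independent; median length 1014 in the list and 3622 in all tested genes). After removal of the gene length trend 9 members were called higher, 8 of them among the 17. The bound of 8 was set before the corrections were run, and by it alone 9 members would argue against length; that reading was changed 2 times after the values were seen, first leaving length and GC content both open. It was not kept for length because 9 is close to the bound and the correction lowered the count in each fit with a library left out (2 to 10, against 3 to 30 uncorrected). The median log2 fold change went from 0.23 to 0.1, with a median standard error of 0.09 before and 0.07 after, and the call of the list ended because the members' fold changes shrank. GC content is argued against: after removal of its trend 20 were called higher, 16 of them among the 17, the median was 0.25, and the count fell in no fit with a library left out (5 to 30, against 3 to 30), where at most 1 member lost its call by the correction. Median GC was 49.8% in the list and 49.9% in all tested genes. The length correction also moved a list without calls. Of 85 ribosomal protein genes 0 were called before it, with a median log2 fold change of 0.04, and 9 were called lower after it (camera adjusted p = 0.0027). The simulated length trend held no other change, so it cannot show whether a true shift of a list would outlast the correction. Length cannot be told apart from age here, and an age effect stays open as a hypothesis.

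With 3 libraries per group there are 10 splits, too few for a share under 0.05. For genes called, the count of splits as large, the real one included, was 1 of 10: the real split called 2835 and the highest of the others 0. For gene lists, it was 7 of 10, so that 6 of the 9 other splits reached the real split's 13, and the highest of them called 17. Each other split had young and old libraries on both sides. Part of the difference between the ages thus stayed in it, and mixed ages widened the spread within its groups. The splits therefore cannot decide on chance for genes or for lists.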
